A study of Mus musculus with 28 samples.

How the data were processed

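Chromosome contacts were measured by circular chromosome conformation capture with sequencing (4C-seq), in which chromatin is cut and religated and all fragments joined to 1 chosen fragment, the viewpoint, are amplified and sequenced. Per the labels' protocols, chromatin was digested with NlaIII and religated, then digested with DpnII and circularised, and amplified by inverse PCR. Cells were of the mouse embryonic stem cell (ESC) line E14Tg2a, kept as ESC or differentiated for 5 days into anterior neural progenitor cells (AntNPC). The series lists 28 samples, and 13 libraries were analysed here, 1 per combination of viewpoint, genotype and cell state; the other samples were not analysed here. Groups were taken from the sample titles.

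Each file holds 1 library as restriction fragments with a value in RPM (reads scaled to the depth of the library), and the authors deposited these values after mapping with HISAT2 to mm10, per the submitters' processing notes; the HISAT2 version and the read filters are not given in the sources used here. All RPM values of a library were whole multiples of its smallest value, within a tolerance of 0.1 (100% of values in each library), so reads per fragment were recovered by division. Recovered totals ran from 1023252 to 7730539 reads per library. The fragment with most reads was taken as the viewpoint. In the library labelled as a Gata6 insertion viewpoint this fragment was that of the Gata6 promoter viewpoint. The planned contact of the insertion with the Gata6 promoter in that library, and the planned window at the Gata6 insertion site, could therefore not be placed. They were replaced, after the data were examined, by the reads of the donor copy of the inserted sequence near Sox1, to which reads from the inserted copy map.

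The main measure was the share of local reads, which are reads within 1 Mb of the viewpoint on its chromosome with 10 kb on each side left out. Targets were windows of 5 kb on each side of a viewpoint fragment or of the annotated start of Six3 or Gria1. Shares have 95% Wilson binomial intervals, and log2 ratios of shares have exact (Clopper-Pearson) conditional intervals. Reads were amplified by PCR without molecular identifiers, so these intervals, and the limit of 3 reads used where none was seen, cover counting error only. With 1 library per condition no test between conditions was made and no p-value is given, and a count test on recovered reads was not run for the same reason. Each log2 ratio was instead placed as a percentile among windows of the same size, in steps of 5 kb, at 0.5 to 2 times the distance of the target in the same libraries, and described as inside or outside their central 95%. Windows with reads in 1 library only were ranked as extremes, and windows overlapping the deleted stretch were left out. Distances were those of mm10 in all libraries, so in del36 targets and windows across the deleted stretch lie nearer than their matching distance. This percentile describes these libraries and is not a test. Carry-over between libraries of 1 viewpoint was estimated, after the data were examined, as the reads in the other libraries times the median rate at which their 200 tallest off-chromosome fragments recurred. Fragments can recur for other reasons, so this estimate is not a measured carry-over. From Six2 promoter WT to del36 the rate was 4.48%. In the longest stretch without fragments of at least 10 reads in Six2 promoter del36, that library had 10 reads where WT had 13484. This low count follows in part from the choice of the stretch, so it says little about the rate. In the stretch chosen from the PE Six3 del36 library, Six2 promoter del36 had 796 reads, of which 661 and 125 lay on the outermost fragments.

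The deleted stretch was taken as the longest stretch without reads between the PE Six3 and Six2 viewpoints in a del36 library. Genes were taken from a RefSeq table of GRCm38.p6, the same assembly as mm10. The table carries no strand, so genes other than the targets were measured over their span with 5 kb on each side. This replaced the planned window at the transcription start. Spans were cut at the 1-Mb limit and at the 10 kb left out around the viewpoint. All protein-coding genes within 1 Mb of a viewpoint were measured. The rule fixed before the data were examined names the viewpoints and targets, the 10 genes highest in the wild type (WT) library, the 5 with the largest log2 ratio each way, and the 3 gene-free 10-kb windows with the largest ratio each way; with 7 to 13 genes in range, the text gives counts with examples. Of the developmental regulators listed beforehand, Epas1 and Zfp36l2 lay outside the range. The planned comparison of starts with and without a CpG island needs a genome sequence and was not run.

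Alternatives were the deposited RPM without rescaling, the share of all reads of the viewpoint chromosome, 25 kb left out on each side of the viewpoint, windows of 10 kb on each side of the target, values capped at the 99th percentile of the viewpoint chromosome, and covered fragment length in place of reads. Leaving out fragments with fewer than 10 reads was added after the data were examined, as were other scales for the gene counts and the Gria1 span without its tallest window. The window ranking was tested on simulated data made from the WT library of the PE Six3 viewpoint, with fragment noise of 1.5 (SD, log2) and the Six2 window changed by a known factor. Among 118 matched windows, the changed window left the central 95% in 0.50% of 200 draws with no change, in 48.5% with a change of 4 times and in 99% with a change of 16 times. With the spread measured between single local fragments of the PE Six3 libraries, 5.54 (SD, log2), these shares were 3%, 8% and 21%, and 43.5% with a change of 64 times. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.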

Results

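The data are 4C-seq contact profiles of 4 viewpoints in mouse cells. The study concerns poised enhancers (PE), regulatory elements of developmental genes that are held inactive in ESC, and the CpG islands (CGI) beside them. The libraries cover a pair of designs. In the first, a stretch holding a domain boundary between Six3 and Six2 was deleted (del36), and ESC were profiled from the Six2 promoter and from PE Six3. In the second, parts of PE Sox1 were inserted near Gata6 or Gria1: its transcription factor binding sites (TFBS), its CGI, or both (TFBS+CGI). Gata6 libraries were from AntNPC at day 5 with the promoter as viewpoint, and Gria1 libraries were from ESC with the insertion site as viewpoint. There was 1 library per condition and no replicate, so differences are between libraries. Total reads ran from 1023252 to 7730539, of which 82.8% to 98.9% lay on the viewpoint chromosome. Local reads ran from 51943 on 544 fragments in the Gria1 CGI library to 1218764 on 1076 fragments in the PE Six3 WT library.

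The del36 libraries had few or no reads of a stretch between Six3 and Six2. From PE Six3, the longest stretch without reads in del36 was chromosome 17 from 85629635 to 85666796 (mm10), 37.2 kb, where the WT library had 42934 reads on 46 fragments. None of 355383 local reads of the del36 library lay there, which follows from the choice of this stretch. From the Six2 promoter, the longest stretch without any reads in del36 was 17.0 kb, from 85637856 to 85654845, inside the first. In this stretch, chosen from the other library, the PE Six3 del36 library had 0 reads too, which allows a share of up to 0.00084%. Counting only fragments with at least 10 reads, the stretch from the Six2 promoter was 37.0 kb, with 10 reads left on 5 fragments against 13484 in WT. This low count follows in part from the choice of the stretch in the same library. Over the whole 37.2-kb stretch, the Six2 promoter del36 library had 796 reads on 7 fragments, 0.334% of its local reads, of which 661 and 125 lay on the outermost fragments. The 37.2-kb stretch began 3.44 kb past the annotated end of Six3 and overlapped the annotated span of Six2 by 4.06 kb.

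The first comparison asks whether the Six2 promoter and PE Six3 were in more contact without the boundary. Six3 is a homeobox gene of forebrain and eye development and Six2 a homeobox gene of kidney progenitors. The viewpoints lie 204 kb apart, at 85689020 to 85689800 (Six2 promoter) and 85485041 to 85485766 (PE Six3). From PE Six3, the window at the Six2 promoter held 0.398% of local reads in WT (95% interval 0.387% to 0.409%) and 2.07% in del36 (2.021% to 2.115%), 5.20 times as much. Reads in this window lay on 8 fragments in WT and 15 in del36. The PE Six3 libraries also differed in local reads, 1218764 on 1076 fragments in WT and 355383 on 1602 in del36. From the Six2 promoter, the window at PE Six3 held 1.36% in WT (1.302% to 1.413%) and 2.112% in del36 (2.06% to 2.17%), 1.56 times as much. Within the del36 libraries these windows stood high for their annotated distance: 4 of 108 matched windows were higher from PE Six3 and 0 of 118 from the Six2 promoter, against 59 and 13 in WT. The matched windows were set by distance on the undeleted chromosome. The deletion brings each target nearer to the viewpoint but leaves windows on the other side in place. The shorter distance could therefore raise this standing.

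On the log2 scale the ratio of del36 over WT was 2.38 (2.33 to 2.43) from PE Six3 and 0.64 (0.57 to 0.71) from the Six2 promoter. Both lay inside the central 95% of matched windows, at percentiles 83.3 and 62.7; the central range ran from -3.37 to 5.38 from PE Six3 and from -3.21 to 6.40 from the Six2 promoter over windows with reads in both libraries. Direction depended on the measure: with 10 kb on each side, the ratio from the Six2 promoter was -0.085 and that from PE Six3 1.97, and with covered length that from PE Six3 was -0.20.

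PE Six3 was also read at the Six3 promoter, 128 kb away on its own side of the boundary. That window held 2.29% of local reads in WT (2.27% to 2.32%) and 4.02% in del36 (3.95% to 4.08%), a log2 ratio of 0.81 (0.78 to 0.84) at percentile 65.6. In del36 none of 64 matched windows was higher, and in WT 6 were. From the Six2 promoter, the Six3 promoter window lies 75.8 kb away, across the deleted stretch. It held 4.96% in WT (4.86% to 5.07%) and 8.26% in del36 (8.15% to 8.37%), 1.67 times as much. This ratio was at percentile 70.3 of 37 matched windows, inside the central 95%. In WT 1 of these windows was higher and in del36 0. The share was larger than that at PE Six3 in both libraries, but PE Six3 lies farther, at 204 kb. In del36 the deletion also brings the Six3 window nearer. For PE Six3 and the Six3 promoter the log2 ratio was -0.31 with covered length.

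The share of signal beyond the deleted stretch was higher in del36 from both viewpoints. From the Six2 promoter it was 37.6% in WT (37.4% to 37.9%) and 52.9% in del36 (52.7% to 53.1%), and from PE Six3 18.8% (18.7% to 18.9%) and 29.5% (29.4% to 29.7%). The log2 ratios were 0.49 and 0.65. Over the same distances on the other side of the viewpoint, the shares were 43.0% in WT and 36.6% in del36 from the Six2 promoter, and 30.2% and 27.8% from PE Six3. The first 50 kb beyond the stretch held 14.7% in WT and 20.5% in del36 from the Six2 promoter, where Six3 lies, and 3.18% and 5.27% from PE Six3, where the Six2 promoter lies. The 50-kb step that holds PE Six3 did not gain share from the Six2 promoter, at 4.56% in WT and 4.37% in del36. The side-to-side log2 change was 0.72 and 0.77 from the Six2 promoter and PE Six3. Between pairs of Gata6 or Gria1 libraries, which carry no deletion, 4 of 12 values at the distance of the first and 1 of 12 at that of the second were as large. With any 1 library left out, these were 1 to 4 of 9 and 0 to 1 of 9. Without the Gria1 CGI library they were 1 of 9 and 1 of 9, so the first count rests largely on that library. These pairs share libraries and differ in their inserts.

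Gene shares were set against gene-free 10-kb windows, whose median log2 ratio was 0.43 from PE Six3 (SD between windows 2.32) and 0.04 from the Six2 promoter (SD 2.90). Genes were summed over wider spans than these windows, so the measures are unlike. From PE Six3, all 4 genes toward Six2 were higher in del36, by about that median and none by 2 times. Six3 was at 0.36, Six2 at 0.35, Srbd1 at 0.37 and Prkce, which encodes a protein kinase C, at 0.48 (log2, gene span in range). Part of the measured Six2 span, and the edge of that of Six3, lay in the deleted stretch. Their del36 shares lack those reads, which lowers these ratios. Of the 9 genes on the other side 3 were higher and 6 lower; Ppm1b, a protein phosphatase gene, was at -0.72, Lrpprc, which encodes a mitochondrial RNA-binding protein, at -0.56 and Abcg8, a sterol transporter gene, at -0.46, while Plekhh2 was at 2.71. From the Six2 promoter, 6 of 8 genes toward PE Six3 were higher, among them Lrpprc at 2.07, Prepl at 1.12, Slc3a1, an amino acid transporter gene, at 1.06, Six3 at 0.53 and Camkmt at 0.50. Six2 itself was at -0.58, with part of its span deleted, and Abcg8 at -2.113. On the other side Srbd1 was at -0.17 and Prkce at 0.27. The range cut some spans, so these values are unlike between viewpoints. Abcg8 was measured over 15923.5 bp from the Six2 promoter and 34031 bp from PE Six3, and Prkce over 500134 and 322618 bp. Among gene-free 10-kb windows, the largest ratios toward the far side were 7.44 at 85775404 to 85785403 from PE Six3, with 26 reads in WT and 1315 in del36, and 9.17 at 84919410 to 84929409 from the Six2 promoter, with 1 and 829 reads. The lowest were -4.41 at 84885404 to 84895403 from PE Six3 and -7.83 at 84799410 to 84809409 from the Six2 promoter.

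**Figure D1:**
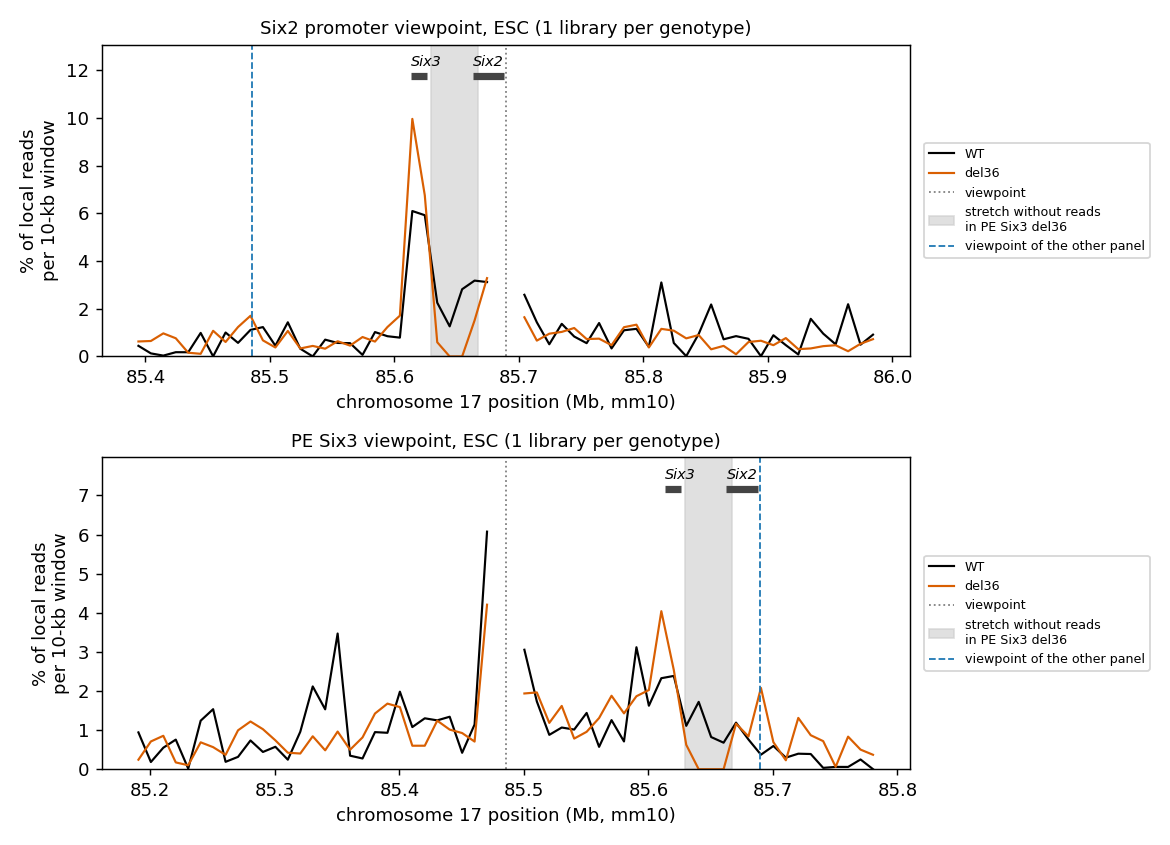
Share of local reads (percent, vertical axis) per 10-kb window along chromosome 17 (Mb, mm10) from the Six2 promoter (top) and PE Six3 (bottom) in WT and del36 ESC, with 1 line per library. The grey band is the 37.2-kb stretch, and at the Six2 promoter the del36 line of the bottom panel stands above the WT line, as the window shares of 2.07% and 0.398% give.

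The Gata6 comparison asks whether the inserted parts of PE Sox1 contacted the promoter of Gata6, a transcription factor gene of endoderm and heart, in AntNPC. The viewpoint is chromosome 18 from 11053305 to 11053963, 0.795 kb past the annotated start of Gata6. Reads from the inserted copy map to the donor locus, as do those of the donor copy itself, and a fragment at chromosome 8 from 12429908 to 12430215, 34.4 kb past the start of Sox1, had reads in all Gata6 libraries. This fragment was chosen for its reads in these libraries, so its counts are not an independent readout of the insert. It had 845 reads in TFBS+CGI and 175 in TFBS, against 5 in CGI and 1 in WT. As shares of local reads these were 0.542%, 0.0906%, 0.0074% and 0.0009%. Among windows of the same size on chromosome 8, the Sox1 window, with reads on any of its fragments, ranked 3 of 470 with reads in TFBS+CGI, 13 of 509 in TFBS, 201 of 464 in CGI and 302 of 394 in WT.

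Relative to local reads, TFBS+CGI was 5.98 times TFBS, a log2 ratio of 2.58 (2.34 to 2.82), at percentile 82.6 of the 895 local fragments read in both libraries. On the deposited scale that log2 ratio was 0.96. Over WT the log2 ratios were 9.23 (6.75 to 14.5) for TFBS+CGI, 6.65 (4.15 to 12.0) for TFBS and 3.04 (-0.12 to 8.60) for CGI, all against a single WT read; percentiles were 98.8, 93.2 and 62.2 among fragments read in both libraries, and 54.1, 44.0 and 59.5 among all local fragments, with those read in 1 library ranked as extremes. On the deposited scale these ratios were 9.61, 8.65 and 3.77. The CGI and WT counts were no larger than the 6.81 and 2.38 reads that the carry-over estimate for this viewpoint gives. Which part of PE Sox1 this fragment belongs to is not given in the sources used here, so a low count does not show that the CGI part lacked contact.

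For genes within 1 Mb of the Gata6 promoter, the direction depended on the scale. As shares of local reads, 2 of 10 genes were higher than in WT in CGI, 3 in TFBS+CGI and 4 in TFBS, and on the deposited scale, which shifts the log2 ratios by 0.73, 0.38 and 2.00, these counts were 6, 4 and 10. Gene-free 10-kb windows had median log2 ratios of 0.45, 0.31 and 0.95 as shares of local reads, with SDs between windows of 2.83, 3.19 and 2.58. All 10 genes lay below these medians. Gene values sum reads over wider spans than single 10-kb windows, so the measures are unlike and this order says little about the genes. Cables1 was at -1.77 in TFBS+CGI, -1.29 in TFBS and -1.22 in CGI (log2 over WT, shares of local reads). Snrpd1, a splicing factor gene, was at -4.54 in CGI, on 19 reads against 726 in WT, and at -0.61 in TFBS+CGI and -0.56 in TFBS. Mib1, which encodes a ubiquitin ligase of the Notch pathway, was at 0.46 in TFBS and 0.24 in TFBS+CGI, and -0.03 in CGI. Gata6 itself, without the part left out around the viewpoint, was at -0.04 in TFBS+CGI, -0.36 in TFBS and -0.35 in CGI. The gene-free window at 11823634 to 11833633 was among the 3 lowest in all comparisons, at -7.86 in TFBS+CGI, -2.74 in TFBS and -5.07 in CGI. All these ratios share 1 WT library.

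**Figure D2:**
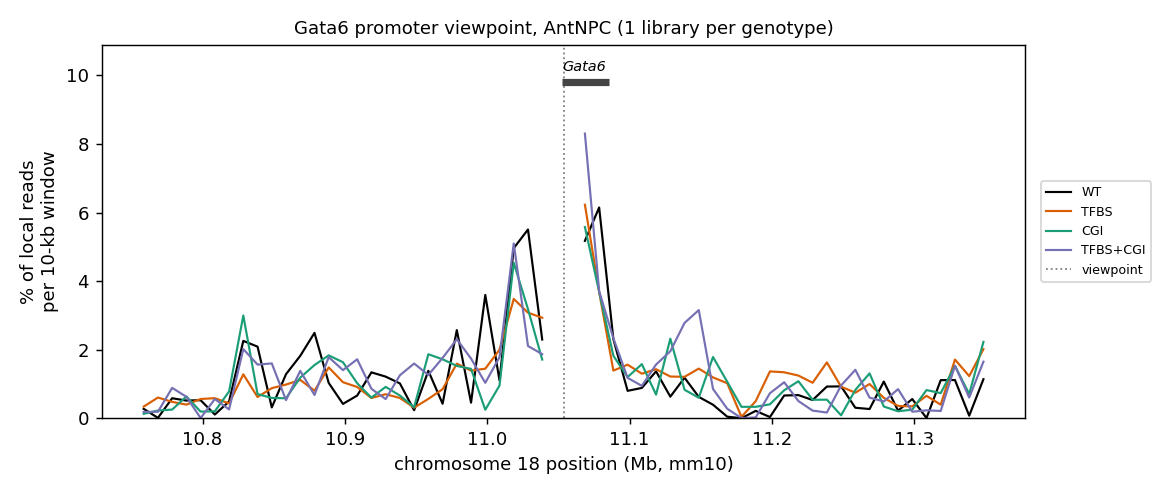
Share of local reads (percent, vertical axis) per 10-kb window along chromosome 18 (Mb, mm10) from the Gata6 promoter in AntNPC, with 1 line per genotype and library. The TFBS+CGI line stands above the others around 80 to 100 kb to the right of the viewpoint, a stretch that held 5.94% of its local reads and 1.80% of those of WT.

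The Gria1 comparison asks whether the insertion site contacted the promoter of Gria1, which encodes an AMPA-type glutamate receptor subunit, in ESC with each insert. The viewpoint is chromosome 11 from 56910361 to 56910414, 101 kb before the annotated start of Gria1. The promoter window held 0.0643% of local reads in WT (0.0504% to 0.0819%), 1.28% in TFBS (1.22% to 1.34%), 0.0116% in CGI (0.0053% to 0.0252%) and 0.239% in the library labelled TFBS+CGI (0.224% to 0.254%). These shares rest on 65, 1662, 6 and 996 reads, and 1 fragment held 50.8%, 81.9%, 100% and 67.7% of them. The carry-over estimate for this viewpoint gives 48.9 of the WT reads and 15.7 in CGI. The CGI count was thus not above that estimate and the WT count largely within it. The log2 ratios over WT were 4.31 (3.95 to 4.69) for TFBS, 1.89 (1.53 to 2.28) for TFBS+CGI and -2.48 (-3.97 to -1.28) for CGI. All lay inside the central 95% of 56 matched windows, at percentiles 87.5, 69.6 and 37.5.

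With 10 kb on each side, all ratios were below 0: the log2 ratio was -0.57 for TFBS, -2.53 for TFBS+CGI and -5.88 for CGI. On the deposited scale it was 6.39 for TFBS, 3.93 for TFBS+CGI and -3.19 for CGI, and with covered length -0.84 for TFBS and -0.21 for TFBS+CGI. At the donor locus, the fragment from 12430220 to 12432553 on chromosome 8 had 709 reads in TFBS, 22 in WT, 3 in TFBS+CGI and 0 in CGI, so the library labelled TFBS+CGI had fewer reads of it than WT; it is called TFBS+CGI here by its label. The 22 and 3 reads were close to the 20.8 and 2.66 that the carry-over estimate from the TFBS library gives. This fragment too was chosen for its reads, and it had 0 reads in the Gata6 libraries. The fragment used at Gata6 had 8 reads in Gria1 TFBS and 0 in Gria1 WT, CGI and TFBS+CGI.

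Of 7 genes within 1 Mb of the Gria1 viewpoint, the Gria1 span was at 1.0771 in CGI, 0.49 in TFBS+CGI and 0.41 in TFBS (log2 over WT). The CGI value rests on the window at 57060388 to 57070387, with 21.8% of local reads: without it the span was at -0.33, or 0.014 with the window left out of the total too. The median of gene-free windows was -2.02 in CGI, 0.02 in TFBS+CGI and 0.89 in TFBS, with SDs of 3.63, 3.87 and 3.22. Among genes with reads in either library, 5 of 7 were higher than in WT in TFBS, 4 of 6 in CGI and 6 of 6 in TFBS+CGI. Nmur2, a neuropeptide receptor gene on the other side, was at 5.05 in TFBS+CGI, 2.38 in CGI and 2.21 in TFBS, on 54 WT reads from 3 fragments. Fam114a2 was at -2.19 in TFBS, -2.22 in CGI and 0.67 in TFBS+CGI. Galnt10, a glycosyltransferase gene, was at -1.54, -1.59 and 0.50 in the same order. Mfap3 was at 1.39, 1.37 and 4.08 and Sap30l at 3.42, 1.58 and 4.84, on 55 and 13 WT reads. In CGI, Nmur2 and Fam114a2 had 144 reads each, of which the carry-over estimate gives 116 and 136. Galnt10, Mfap3 and Sap30l had 164, 73 and 20 against 89.2, 60.2 and 24.1. These CGI ratios thus largely rest on reads within that estimate. Hand1, a transcription factor gene of heart and placenta, had 24 reads in TFBS and 0 in the other libraries. In CGI, 10 fragments held 68.9% of local reads, against 24.2% in WT. The gene-free window at 57590388 to 57600387 had 3700 reads in WT, 2 in CGI and 1 in TFBS+CGI.

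**Figure D3:**
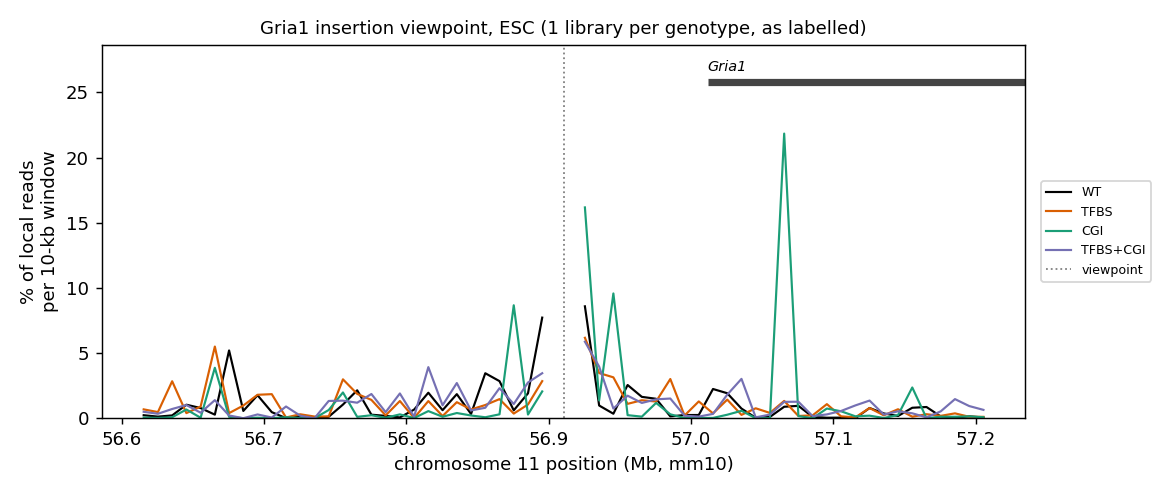
Share of local reads (percent, vertical axis) per 10-kb window along chromosome 11 (Mb, mm10) from the Gria1 insertion site in ESC, with 1 line per genotype and library as labelled. The CGI line is carried by a few tall windows, the highest at 21.8% of its local reads inside Gria1.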

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

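The tests of carry-over and of the donor locus, and the split of the tall fragments by chromosome, were chosen after the results were seen; the test of fragment density around both tall fragments was fixed before.

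The library labelled as an insertion viewpoint with CGI at Gata6 in ESC stands outside the comparisons, because 83.1% of its reads lay on the Gata6 promoter fragment. It had 4 reads of the donor fragment near Sox1.

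Both Six2 promoter libraries held tall fragments on other chromosomes, outside the measured range. A fragment on chromosome 8 from 11593412 to 11593898, 17.7 kb from Ankrd10, had 267759 reads in WT and 179012 in del36, and a fragment in Prrc2b, on chromosome 2 from 32220400 to 32220481, had 63107 and 126635. Carry-over between the libraries is argued against, since the smaller count was up to 66.9% of the larger and the direction differed between the fragments. A second priming site would act as another viewpoint and could enrich its neighbours: the density of covered fragments within 100 kb was 4.26 times that of the rest of the chromosome in the median over both, above the 3 times set beforehand for such a site; by fragment it was 6.47 times at Prrc2b and 1.61 times at the chromosome 8 fragment, which leaves the latter open. The median over both thus lies between unlike fragments and describes neither. At Prrc2b the ratio rests on 6 covered neighbours in each library, and at the chromosome 8 fragment on 2 in WT and 1 in del36. Contact between chromosomes could also raise the density, and no biological explanation was tested.

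Few reads of the donor fragments near Sox1 appeared in 5 of the 6 other Gata6 and Gria1 libraries besides those with at least 100 such reads. Carry-over is a candidate source: 35 reads were seen in all and 37.7 were expected from the rates at which 200 other off-chromosome fragments recurred, a ratio of 0.93 (95% Poisson range 26 to 50 reads). Contact with Sox1 on its own chromosome stays open in the libraries with at least 100 donor reads: fragments within 50 kb, other than both donor fragments, held at most 0.237% of the donor reads (1.13% with the adjoining donor fragment), but only 4.76% to 15.0% of other off-chromosome fragments with at least 100 reads had neighbours that reached 10%. In the libraries with few it stays open too: such fragments held 40 reads against the 35 donor reads (114.3%), all 40 in the Gata6 CGI library on 2 fragments. Contact with Sox1 that all genotypes share would also be read in WT, which had 1 donor read at Gata6 and 22 at Gria1. TFBS+CGI and TFBS had 845 and 175 at Gata6, and TFBS had 709 at Gria1, but each condition has 1 library. An inserted copy near the viewpoint remains open for the TFBS and TFBS+CGI libraries at Gata6 and the TFBS library at Gria1. The donor fragments were chosen for their reads in these libraries and differ between Gata6 and Gria1, so the counts cannot decide this.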

How the results depend on the processing

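Across 12 log2 ratios of targets, far sides and the inserted sequence, 74 alternative values were computed, 66 of them planned and 8 added after the data were examined. In all, 43 stayed within the counting interval of the reported ratio, including all 8 without fragments of fewer than 10 reads. Another 31 moved beyond it, and 7 changed sign. Causes were not tested. Those that stayed include the inserted sequence with 10 kb on each side, which could not move because its target is a single fragment. Ratios over the single WT read have intervals as wide as -0.12 to 8.60, so a shift from 6.65 to 8.65 counted as staying. On the deposited scale, the ratio was 1.19 for the Six2 promoter at PE Six3, 1.04 for its far side, 6.39 and 3.93 at the Gria1 promoter for TFBS and TFBS+CGI, and 0.96 for the inserted sequence in TFBS+CGI over TFBS. As a share of the viewpoint chromosome, these were 1.18, 1.03, 6.44, 3.92 and 0.90, and PE Six3 gave 2.56 at the Six2 promoter, 0.99 at the Six3 promoter and 0.83 for the far side. With 25 kb left out, PE Six3 gave 0.76 at the Six3 promoter and 0.60 for the far side, and the Six2 promoter 0.48 for the far side. With 10 kb on each side of the target, the Six2 promoter gave -0.085 at PE Six3, PE Six3 gave 1.97 at the Six2 promoter and 0.43 at the Six3 promoter, and the Gria1 promoter -0.57 for TFBS, -5.88 for CGI and -2.53 for TFBS+CGI. With capped values, PE Six3 gave 0.49 at the Six3 promoter and the Six2 promoter 0.47 for the far side. With covered length, the Six2 promoter gave 0.17 at PE Six3 and 0.21 for the far side, PE Six3 gave -0.20, -0.31 and 0.41 at the Six2 promoter, the Six3 promoter and the far side, and the Gria1 promoter -0.84 for TFBS and -0.21 for TFBS+CGI. The far-side shares kept their direction under every alternative run. Covered length has no value for the single donor fragment, leaving out low fragments none for comparisons with a single read or for CGI at Gria1, and no alternative was run for the library labelled as a Gata6 insertion viewpoint or for the Six2 promoter at the Six3 promoter. Low counts limit the Gria1 CGI library, with 6 reads at the promoter, and the Gata6 WT library, with 1 read of the inserted sequence. No paired analysis was possible because each condition has 1 library.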

Other observations

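The tests of removal of the stretch and of distance were chosen after the result was seen; that of other library pairs was fixed before. The stretch below was also chosen after its values were seen.

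Around the Gata6 promoter, TFBS+CGI stood apart 80 to 100 kb to the right, on chromosome 18 from 11133634 to 11153633, past the end of Gata6. It held 5.94% of local reads (5.82% to 6.05%), against 2.66% in TFBS, 1.80% in WT and 1.43% in CGI. The log2 ratios over WT were 1.72 for TFBS+CGI, 0.56 for TFBS and -0.34 for CGI, at percentiles 93.9, 55.1 and 24.5 of 49 matched windows. Over the same distance to the left the shares were 3.02% in TFBS+CGI, 1.41% in TFBS, 1.81% in WT and 3.59% in CGI. The position of the insert is not given in the sources used here.

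The far side of the boundary gained share in del36 from both viewpoints relative to the other side, by 0.72 from the Six2 promoter (0.30 to 1.13 in a bootstrap of 50-kb blocks) and 0.77 from PE Six3 (0.224 to 1.301) on the log2 scale. Differences between any 2 libraries stay open: 6 of 24 values of other pairs, up to 1.13 in size, reached the 0.72 and 3 the 0.77. At the matching distances these were 4 of 12 and 1 of 12. With any 1 library left out, they were 3 to 6 and 1 to 3 of 18, or 1 to 4 and 0 to 1 of 9. Without the Gria1 CGI library they were 3 and 1 of 18, up to 1.07 in size. The pairs share libraries and differ in their inserts. Removal of the stretch from the total would raise both sides alike, by 0.123 from the Six2 promoter and 0.052 from PE Six3. It would leave the difference at 0, so removal alone cannot make the 0.72 and 0.77. Spread between libraries could, and the bootstrap does not hold that spread. The shorter distance alone could give 0.65 from the Six2 promoter, inside the bootstrap range, and 0.159 from PE Six3, below it, and stays open too. Loss of the boundary, which the design names, remains a hypothesis that replicate libraries could test.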
